A study of Mus musculus with 8 samples.

How the data were processed

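Alveolar macrophages of mice were measured by bulk RNA sequencing in 8 libraries, 2 for each of 4 groups. Each library was made from a pool of 3 mice or 3 cultures, per the labels, so the pools and not single animals were the units of replication. RNA was isolated with a miRNeasy kit, cDNA was amplified from 2 ng of total RNA by single-primer isothermal amplification (NuGEN Ovation RNA-Seq V2), and libraries were made with the Ovation Ultralow kit, per the labels' protocols. Bowtie, HTSeq version 0.6.1, R version 3.3 and the genome build mm10 (GRCm38) are named in the submitters' processing notes, which give no further parameters. The deposited values were counts of reads per gene, given as whole numbers for 37310 Ensembl gene IDs, of which 22497 had a count in at least 1 library. The total per library ran from 6546272 (exAM replicate 1) to 9154128 (texAM replicate 1) counts. The table's columns carried the group names and replicate numbers of the labels, except that the texAM columns were abbreviated, and all 8 were matched to a group. Gene symbols were those of the deposited table, and genes without one kept their Ensembl ID. Positions and transcript lengths were taken from GENCODE M21, annotated on GRCm38, in which 32620 of the IDs (87.4%) were found. All positions below are GRCm38 coordinates of the annotated gene, counted from 1.

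The groups, tests, gene lists and alternatives were fixed before the data were examined. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with too few counts were left out by filterByExpr with its default minimum of 10 counts, which left 14537 tested genes. Libraries were scaled by TMM. A quasi-likelihood negative binomial model with robust dispersion estimates was fitted to all 8 libraries with 1 coefficient per group, which left 4 residual degrees of freedom, and each of 6 pairs of groups was tested by the quasi-likelihood F test. The biological coefficient of variation was 0.22. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Levels are given as CPM, counts scaled by the effective (TMM) library size, as mean ± SD over the 2 libraries of a group. A fold against a group with 0 counts in both libraries was computed against 3 counts over the group and is written as at least that fold, and a fold against 1 to 3 counts is given with a 95% counting interval. Intervals and floors cover counting error only.

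In all, 21 lists of genes (pathways and cell programmes) and 7 lists of markers of other cells or of sex were tested by camera with a preset inter-gene correlation of 0.01, adjusted over the 21 or the 7 lists. The same test was also run with the correlation estimated from the data, which is the stricter form with 2 libraries per group. How much of the difference of cultured cells remained after transfer was measured as the slope through the origin of the log2 fold change of texAM over tAM on that of exAM over HostAM, over genes called in the latter pair, so that the 2 axes shared no library. A slope of 1 would mean that the whole difference was kept and 0 that none was, provided that all genes moved alike. Genes were named by a fixed rule. For exAM against tAM, texAM against exAM and texAM against tAM, the 10 largest called changes in each direction were taken, and for each comparison with HostAM the 5 largest. These genes needed at least 10 CPM in the higher group and no overlap between libraries. Genes with predicted or clone names were passed over. Added to these were the 2 largest called changes per direction in each list, any member of the lists of alveolar macrophage identity, self-renewal and cell markers, and Ptprc. A few genes outside the rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

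The scripts were tested on simulated counts drawn from the real means and library sizes. For texAM against tAM, 43.9% of genes changed 2-fold, 72.2% of genes changed 4-fold and 79.1% of genes changed 8-fold were recovered over 5 simulations with 14101 tested genes, with 5.5% of the calls false. For exAM against tAM the shares of the changed genes recovered were 42.7%, 69.9% and 76.7%, with 5.7% of the calls false and 13919 genes tested. In each comparison 335, 335 and 330 genes were changed 2-fold, 4-fold and 8-fold over the 5 simulations together. With fewer changed genes the adjusted threshold is stricter, so these shares may overstate what could be recovered where few genes were called. Simulated slopes of 0, 0.2 and 0.5 were estimated as 0.001, 0.185 and 0.477. The alternatives were no filter, a minimum of 50 counts, DESeq2 1.42.0 size factors, library size without TMM, the replicate number as a block, leaving out each library, the DESeq2 Wald test, fits of only the 4 libraries compared, a 2-fold minimum, the other pair of contrasts for the slope, and leaving out mitochondrial, ribosomal RNA and haemoglobin genes. The last of these took out only 7 genes with counts, while the table held 37 mitochondrial IDs. It therefore does not show how the results depend on mitochondrial genes. Alternatives added after seeing the data were leaving out genes over 0.5 counts per base of their longest transcript, counts corrected for filled start positions, and a slope from log2 CPM with a prior count of 2. The correction took each gene to hold 2 start positions per base, 1 on each strand. Figures were drawn with matplotlib 3.10.9 in Python 3.11.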

Results

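The data describe alveolar macrophages, the resident phagocytes of the airspaces, in 4 states. Expanded cells (exAM) came from C57BL/6 mice and were grown outside the body for 2 months. Transplanted expanded cells (texAM) were exAM instilled into the airways of Ly5.1 mice, which carry another allele of CD45, and sorted from whole lung 4 months later. Transplanted cells that were never cultured (tAM) had also spent 4 months in a recipient lung, and resident cells of the Ly5.1 strain (HostAM) were sorted by their own CD45 allele. Whether the mice that gave HostAM had received cells or PBS is not stated for these libraries, and comparisons with HostAM cannot separate the 2. The 3 groups from lung were sorted as SiglecF-positive and CD11c-positive cells, and exAM were not sorted. Each group held 2 libraries, with 6546272 to 9154128 counts per library. The first principal component carried 66.8% of the variance and set the 2 exAM libraries apart from the 6 lung libraries, while the second, with 9.2%, ran from HostAM through tAM to texAM.

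**Figure D1:**
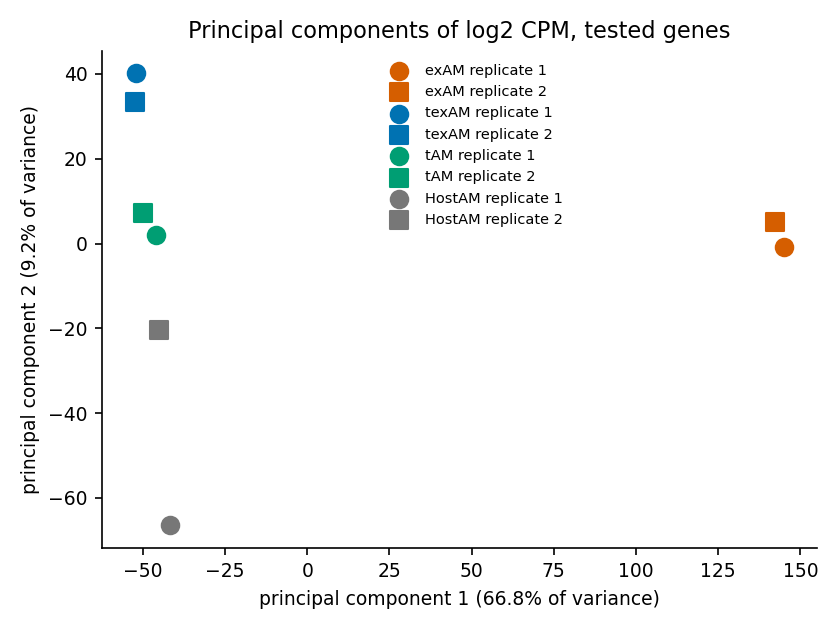
First 2 principal components of log2 CPM over the 14537 tested genes, 1 point per library, circles for replicate 1 and squares for replicate 2. The exAM libraries lie alone on the right of component 1, and HostAM replicate 1 lies at the bottom of component 2.

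The first comparison asked how cells expanded in culture differed from donor cells that had stayed in a lung. In exAM, 3124 genes were higher and 3378 lower than in tAM, 44.7% of the tested genes. With an estimated correlation the list of class II and co-stimulation genes was called lower (adjusted p = 0.0254), and that of glycolysis and hypoxia, higher at the preset correlation, was not called (adjusted p = 0.0953). Members of the list of alveolar macrophage identity went both ways. Csn2, a milk casein (ENSMUSG00000063157, chromosome 5, 87692624 to 87699630), stood at 318 ± 13.2 CPM in exAM (n = 2) and 0 counts in every lung library, at least 1750-fold higher. The collagen gene Col24a1 at 174 ± 41.8 CPM, the fatty acid elongase Elovl7 at 141 ± 43.0 CPM, the serpin Serpinb9b at 116 ± 60.2 CPM and Bex1 at 115 ± 18.6 CPM also had 0 counts in tAM. The same held for Vsig8, the neuropeptide Npy, the actin cross-linker Flnc and Tmeff1, which reached 69.3 to 96.6 CPM in exAM. The collagenase Mmp13 was at 489 ± 189 CPM against 0.125 ± 0.177 CPM in tAM, 4000-fold (counting interval 1110 to 33000).

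Antigen presentation genes fell. Of 16 tested members of the list of MHC class II and co-stimulation genes, 14 were lower in exAM and 1 was higher, both over all genes and adjusted over the list alone, with a median log2 change of -3.15. H2-Eb1, a chain of the MHC class II molecule, stood at 0.806 ± 0.170 CPM in exAM and 174 ± 17.2 CPM in tAM, 213-fold lower, and H2-Ob was at least 21.3-fold lower. Ciita, the master regulator of class II genes, chosen here after its values were seen, was at 2.23 ± 1.21 CPM against 78.3 ± 14.4 CPM. The member that rose was Cd274, the checkpoint ligand PD-L1, from 467 ± 15.5 CPM to 834 ± 20.5 CPM. This was the only list of the 21 that was called with an estimated correlation (adjusted p = 0.0254). Most of the called dendritic cell markers were also lower in exAM, while Clec9a was higher. The share of other cells in these bulk libraries was not measured, so their part in the fall of class II genes is not known.

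Glycolysis and hypoxia genes rose as a list, with 21 of 29 members higher and 2 lower, the same counts adjusted over the list alone, and a median log2 change of 1.08. Camera gave an adjusted p of 6.49e-07 with the preset correlation, and adjusted p = 0.0953 with an estimated correlation. Adm, which encodes adrenomedullin, was at least 29.2-fold higher, and Egln3, an oxygen sensor, was at 31.5 ± 33.4 CPM against 0.483 ± 0.0264 CPM. The glucose transporter Slc2a1, chosen after its values were seen, was at 519 ± 22.4 CPM against 77.7 ± 22.4 CPM. Gapdh and Pfkp fell, Gapdh from 36.9 ± 3.61 CPM to 18.7 ± 2.18 CPM. The list of genes of the NRF2 response to oxidative stress was also called higher, with 11 of 27 members up and 1 down and a median of 0.35 (adjusted p = 0.571 with an estimated correlation). Its member Slc7a11, the cystine transporter, was at 431 ± 72.0 CPM against 112 ± 29.4 CPM.

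Regulators of self-renewal rose with 7 of 11 members higher and 2 lower, and a median of 0.97 (adjusted p = 0.00513, and adjusted p = 0.305 with an estimated correlation). Without a filter on low counts this list was not called (adjusted p = 0.0538, median 0.52). The cyclin Ccnd1 rose from 14.3 ± 1.80 CPM to 464 ± 147 CPM, Ccnd2 from 514 ± 44.0 CPM to 1005 ± 104 CPM, Myc from 183 ± 41.5 CPM to 266 ± 13.8 CPM and Id3 from 3.72 ± 1.65 CPM to 62.9 ± 2.95 CPM. Maf, a repressor of self-renewal, was at 1.83 ± 1.13 CPM in exAM against 18.7 ± 9.03 CPM. Genes of the cell cycle did not pass as a list, with 2 of 34 members higher, 13 lower and a median of -0.38. The proliferation marker Mki67 was 1.34-fold higher, while the replication licensing gene Cdc6 fell 3.06-fold and the mitotic activator Cdc20 3.45-fold.

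Of the 40 tested members of the list of alveolar macrophage identity, 21 were higher and 10 lower in exAM (21 and 12 adjusted over the list alone), its median was 0.33, its mean -0.57 and camera's direction was down (adjusted p = 0.986). The scavenger receptors Marco and Cd36 were higher, Cd36 at 749 ± 112 CPM against 242 ± 1.84 CPM, and the eosinophil-type ribonuclease Ear6 rose 12.4-fold. Epcam, an adhesion molecule of epithelia, was at 173 ± 10.7 CPM in tAM and 0 counts in exAM, at least 710-fold lower. The keratin Krt79 fell 117-fold, the lipid droplet gene Cidec stood at 4.57 ± 0.569 CPM against 273 ± 22.4 CPM, and the fatty acid binding protein Fabp1 at 5.89 ± 3.31 CPM against 98.4 ± 3.92 CPM. Siglecf itself was at 186 ± 59.4 CPM against 338 ± 8.05 CPM, and Pparg, the nuclear receptor that directs the lineage, at 238 ± 5.15 CPM against 201 ± 2.69 CPM (adjusted p = 0.122). Of these members, 19 held over 1 count per base of their longest transcript, a level at which counts hardly followed library size. Without genes over 0.5 counts per base, the 9 members left, 3 higher and 3 lower, had a median of -0.70 and the list was called lower (adjusted p = 0.00578, in a range of 0.00578 to 0.993 over the alternatives).

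Lysosomal genes rose, with 25 of 35 members higher and none lower (26 adjusted over the list alone) and a median of 0.52 (adjusted p = 6.79e-08, and adjusted p = 0.486 with an estimated correlation). The galactosidase Gla rose 2.88-fold and the proton pump subunit Atp6v1h 2.29-fold. In this list 17 members were over 1 count per base. Of the 11 members under 0.5 counts per base, 7 were higher and 0 lower, with a median of 0.85. Sterol efflux and LXR target genes fell, with 10 of 18 members lower, 3 higher and a median of -1.26 (adjusted p = 0.000483, and adjusted p = 0.326 with an estimated correlation). Apoe, the lipid carrier, was at 0.326 ± 0.0242 CPM against 60.6 ± 13.03 CPM, and Apoc1 fell with it, while the sterol hydroxylase Ch25h rose 3.76-fold. Fatty acid oxidation and PPAR targets were split, 6 of 25 higher and 11 lower (7 and 13 adjusted over the list alone) with a median of -0.38. Pdk4, which spares glucose, fell 286-fold (counting interval 78.8 to 2360) and Plin4 at least 39.3-fold.

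Matrix and phagocytosis genes also went both ways. In the list of extracellular matrix and remodelling genes 14 of 24 were higher and 8 lower (16 and 8 adjusted over the list alone), with a median of 0.60 (adjusted p = 0.0162, and adjusted p = 0.571 with an estimated correlation). The elastase Mmp12 was at 617 ± 69.4 CPM against 21.5 ± 8.29 CPM, and the fibronectin gene Fn1 fell from 1426 ± 115 CPM to 9.69 ± 9.34 CPM. Among 33 pattern recognition and phagocytosis genes 14 were higher and 12 lower, with a median of 0.19 (adjusted p = 0.0188, and adjusted p = 0.486 with an estimated correlation). The complement receptor C3ar1 rose 45.9-fold and the scavenger receptor Msr1 25.3-fold, while Tlr9 fell 10.8-fold. Of 19 TGF-beta targets 8 fell and 6 rose (9 and 6 adjusted over the list alone), with a median of -0.28 (adjusted p = 0.0188, and adjusted p = 0.549 with an estimated correlation). Pmepa1, a feedback inhibitor of the pathway, fell from 192 ± 3.55 CPM to 3.40 ± 1.75 CPM. Without exAM replicate 1 these 3 lists had adjusted p of 0.17, 0.206 and 0.0704, and without exAM replicate 2 TGF-beta targets had adjusted p = 0.253. Without a filter on low counts pattern recognition genes (adjusted p = 0.143) and TGF-beta targets (adjusted p = 0.295) were not called, nor were TGF-beta targets in a fit of the 4 libraries (adjusted p = 0.0554).

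The other lists were not called. Inflammatory mediators fell in 13 of 27 members and rose in 7, with the chemokine Ccl2 at 119 ± 24.8 CPM against 1.37 ± 1.44 CPM and the cytokine Il12b at least 16.3-fold lower. Markers of monocytes and other macrophages were lower in 13 of 27 members and higher in 8, among them the complement gene C1qa, at least 14.6-fold lower, and Lyve1, at 17.1 ± 1.84 CPM. Interferon-stimulated genes fell in 12 of 35 members and rose in 3, with Slfn5 13.9-fold higher and Slfn1 53.0-fold lower (counting interval 14.4 to 442). Arg1, an enzyme of alternative activation, was 31.3-fold higher, and the stress factor Atf3 9.80-fold higher, while Fosb fell 30.7-fold. The amino acid synthesis gene Asns was 11.2-fold higher. Cholesterol synthesis genes rose in 8 of 24 members and fell in 4, with Dhcr7 3.38-fold higher. Of the oxidative phosphorylation list 9 of 28 members were higher and 1 lower (8 and 1 adjusted over the list alone), and of the ribosomal proteins 4 of 38 were higher (0 adjusted over the list alone). Without exAM replicate 1 the cell cycle list (adjusted p = 0.00923, lower) and the stress response list that holds Asns (adjusted p = 0.018, higher) were called. Without exAM replicate 2 oxidative phosphorylation (adjusted p = 0.0126) and ribosomal proteins (adjusted p = 0.00371, and 0.0259 without tAM replicate 2) were called higher. Without a filter on low counts the cell cycle list was called lower (adjusted p = 0.0252), and oxidative phosphorylation (adjusted p = 0.00447) and ribosomal proteins (adjusted p = 0.000216) were called higher.

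Markers of other cells moved with this comparison. Transcripts of lung epithelium were lower in exAM in 14 of 19 tested members and higher in 3, and those of lymphocytes in 8 of 12 and 1. The secretory genes Bpifa1 and Cyp2f2, at 125 ± 33.9 CPM and 61.3 ± 30.4 CPM in tAM, and the T cell receptor component Cd3e, at 41.8 ± 21.4 CPM, had 0 counts in exAM, as had Ccr7, Il18r1, Tppp, Tmem229a, Ikzf3 and the haemoglobin gene Hbb-b1. Red cell and platelet markers were lower in 5 of 7 members and dendritic cell markers in 7 of 16, with 1 higher. The opposite direction was seen for endothelial and stromal markers, 5 of 10 higher and 2 lower, with Pdgfra at 30.5 ± 15.5 CPM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were counted in both exAM libraries, Ddx3y at 9.27 ± 0.228 CPM, and had 0 to 2 counts in each lung library. Ptprc, which encodes CD45 (chromosome 1, 138062861 to 138175708), stood at 483 ± 26.0 CPM in exAM and 750.0 ± 47.3 CPM in tAM.

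The median log2 change of all tested genes was -0.09 in this comparison, and scaling by library size alone moved the share of called genes that were higher from 48% to 34.5%. At a minimum of 2-fold, 1437 genes were higher and 2370 lower.

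**Figure D2:**
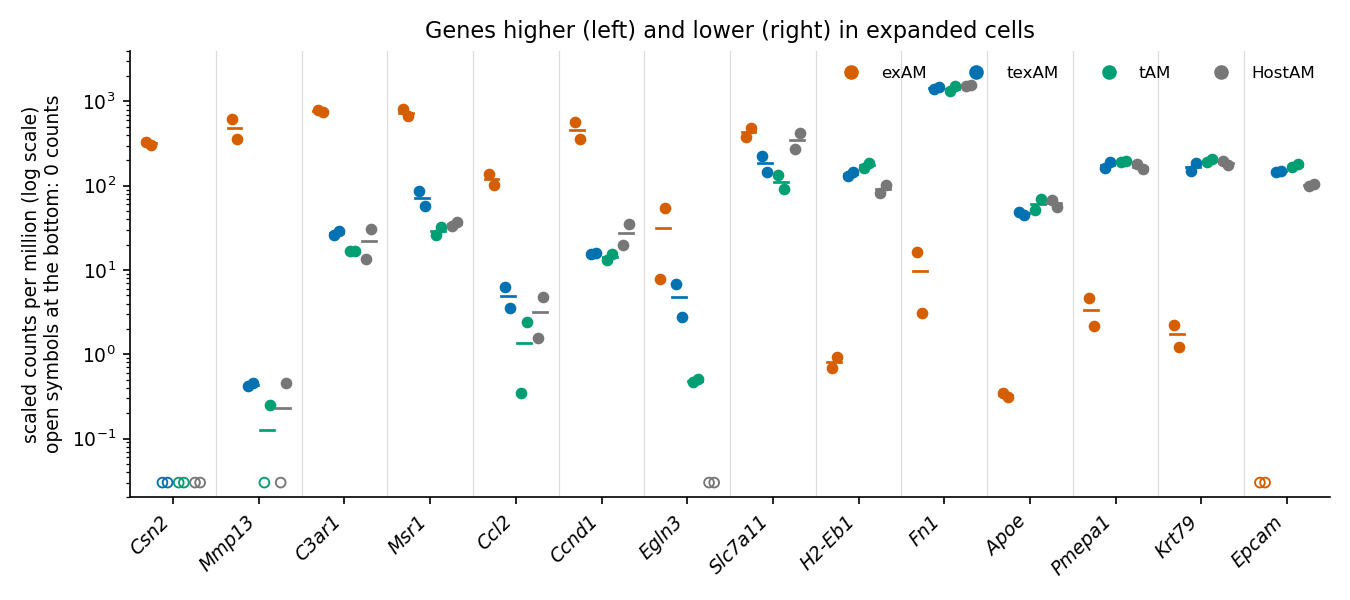
TMM-scaled CPM on a log axis for 14 named genes, 1 point per library and a line at the mean of each group (n = 2). In each of the 8 genes on the left exAM lie above the group means of all lung groups, with Slc7a11 in HostAM the nearest, and in the 6 on the right exAM lie lowest.

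The second comparison set expanded cells after 4 months in a lung against expanded cells in culture. Ddx3y had 55 and 59 counts in the exAM libraries and 0 in those of texAM. The other Y-linked genes counted in exAM also had 0 counts in texAM. The pools sequenced as exAM thus held RNA of male cells that the pools recovered from the lung did not show. In texAM 3372 genes were higher and 2982 lower than in exAM, and 11 lists were called. The exAM libraries enter this comparison and the first with opposite signs, so lists called in opposite directions in the 2 comparisons are not separate results. Of the 16 class II and co-stimulation genes 15 were higher in texAM (15 adjusted over the list alone), with a median of 3.39 (3.13 with members at 0 set to their bound). H2-Eb1 was at 137 ± 11.4 CPM. Camera gave adjusted p = 4.23e-16, and adjusted p = 0.0267 with an estimated correlation. Fn1 rose to 1453 ± 68.5 CPM, Apoe to 46.9 ± 2.00 CPM, Krt79 to 169 ± 27.2 CPM, Epcam to 149 ± 3.75 CPM and Pdk4 to 60.4 ± 2.08 CPM. The casein gene Csn2 had 0 counts in both texAM libraries, at least 1940-fold lower than in exAM, and Col24a1, Serpinb9b, Npy, Flnc, Slc6a12, Layn, Nrcam and Dok7 also fell to 0 counts. Flrt2 fell 3990-fold (counting interval 715 to 157000). Mmp13 fell to 0.437 ± 0.0273 CPM, C3ar1 to 27.8 ± 2.35 CPM and Itgam, an integrin of other macrophages, from 974 ± 215 CPM to 84.0 ± 21.3 CPM.

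Glycolysis and hypoxia genes fell in 22 of 29 members (median -1.07, adjusted p = 7.15e-07, and adjusted p = 0.0941 with an estimated correlation), with Adm 19.4-fold lower. Lysosomal genes fell in 28 of 35 members (30 adjusted over the list alone) and none rose (median -0.62, adjusted p = 3.34e-11, and adjusted p = 0.357 with an estimated correlation), among them Gpnmb 2.39-fold. Self-renewal regulators fell in 7 of 11 members and rose in 3 (median -0.83, adjusted p = 0.0119, and adjusted p = 0.357 with an estimated correlation), with Ccnd1 at 15.7 ± 0.131 CPM and Maf up to 40.1 ± 7.74 CPM. NRF2 genes fell in 15 of 27 members and none rose (adjusted p = 0.0109, and adjusted p = 0.48 with an estimated correlation). Sterol efflux and LXR targets rose in 10 of 18 members and fell in 3 (median 1.23, adjusted p = 0.0109, and adjusted p = 0.357 with an estimated correlation). TGF-beta targets rose in 9 of 19 members and fell in 5, adjusted p = 0.0109, and adjusted p = 0.357 with an estimated correlation. Among the remaining called lists, pattern recognition genes fell in 15 of 33 members and rose in 9 (adjusted p = 0.0124, and adjusted p = 0.357 with an estimated correlation), and matrix genes fell in 14 of 24 and rose in 8 (adjusted p = 0.02, and adjusted p = 0.517 with an estimated correlation). Camera's direction for both was down and their medians were -0.35 and -0.52, while the mean of the matrix list was 0.08. Ribosomal protein genes fell in 17 of 38 members (18 adjusted over the list alone) and oxidative phosphorylation genes in 9 of 28, with 1 higher. Their medians were -0.41 and -0.32, with adjusted p = 0.00964 and 0.0215, and adjusted p = 0.689 and 0.517 with an estimated correlation. Without texAM replicate 1 oxidative phosphorylation (adjusted p = 0.0601) and matrix genes (adjusted p = 0.0656) were not called, nor were pattern recognition (adjusted p = 0.0853) and matrix genes (adjusted p = 0.186) without exAM replicate 1, or TGF-beta targets (adjusted p = 0.124) without exAM replicate 2. Other lists gained calls. The stress response list was called lower without exAM replicate 1 (adjusted p = 0.00274), without texAM replicate 2 (adjusted p = 0.0426), with the replicate number as a block (adjusted p = 0.0487) and without a filter (adjusted p = 0.00979). Called higher were inflammatory mediators without texAM replicate 2 (adjusted p = 0.0466), without a filter (adjusted p = 0.0327) and without genes over 0.5 counts per base (adjusted p = 0.0382), cell cycle genes without exAM replicate 1 (adjusted p = 0.0112) and without a filter (adjusted p = 0.0327), and alternative activation without exAM replicate 1 (adjusted p = 0.049).

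The alveolar identity list was again split, with 9 of 40 members higher in texAM and 23 lower (10 and 23 adjusted over the list alone), a median of -0.45, a mean of 0.46 and no call (adjusted p = 0.425). Without genes over 0.5 counts per base it was called higher (median 0.55, adjusted p = 0.0181), and it was called lower without exAM replicate 2 (adjusted p = 0.00648) and without a filter (adjusted p = 0.00288), in a range of 0.00288 to 0.997 over the alternatives. The largest gains named by the rule included Il18r1, Bpifa1, Cyp2f2, Cd3e, Sh2d2a, Ccr7, Ikzf3 and Tcf7, at 51.9 to 156 CPM in texAM and 0 counts in exAM. Of the marker lists, lung epithelium was higher in 15 of 19 members and lower in 2, lymphocytes in 11 of 12 and 1, dendritic cells in 9 of 16 and 3, granulocytes in 3 of 6 and 1, endothelium and stroma in 3 of 10 and 4, and sex-linked genes in 1 of 5 and 4. Red cells and platelets were higher in 6 of 7 members and lower in 0. The share of called genes that were higher was 53.1%, and 68.1% with scaling by library size alone, and the median log2 change of all genes was 0.11. At a minimum of 2-fold, 2428 genes were higher and 1223 lower.

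The cultured state was also compared with resident cells of the recipient strain. In exAM 3034 genes were higher and 3383 lower than in HostAM, with Csn2, Flrt2, Col24a1, Serpinb9b and Bex1 the largest gains and the secretory genes Bpifa1, Cyp2f2, Clca1 and Bpifb1 and Epcam the largest losses. Lists were called as against tAM, 7 higher and 3 lower, except that NRF2 genes were not called (adjusted p = 0.29) and that ribosomal proteins (15 of 38 higher, adjusted p = 0.00797) and oxidative phosphorylation (9 of 28 higher, adjusted p = 0.0298) were. With an estimated correlation, only class II and co-stimulation genes were called (14 of 16 lower, adjusted p = 0.0284). The next lowest value was that of glycolysis and hypoxia (22 of 29 higher, adjusted p = 0.0613 with an estimated correlation). Without exAM replicate 1 matrix (adjusted p = 0.171) and pattern recognition genes (adjusted p = 0.173) were not called, without exAM replicate 2 TGF-beta targets (adjusted p = 0.185) were not, and without HostAM replicate 1 or 2 matrix genes were not (adjusted p = 0.0683 and 0.0604), nor oxidative phosphorylation without HostAM replicate 2 (adjusted p = 0.0661). NRF2 genes were called higher without exAM replicate 2 (adjusted p = 0.027). The alveolar identity list was called higher without exAM replicate 2 (adjusted p = 0.0111) and without a filter (adjusted p = 0.0168), and lower without genes over 0.5 counts per base (adjusted p = 0.0117). Cell cycle genes were called lower in 5 alternatives, without exAM replicate 1 (adjusted p = 0.00228), texAM replicate 2 (adjusted p = 0.0451), HostAM replicate 2 (adjusted p = 0.0316) or a filter (adjusted p = 0.00837) and with library size alone (adjusted p = 0.0422). The stress response list was called higher without exAM replicate 1 (adjusted p = 0.00559) and without a filter (adjusted p = 0.025). Against each of the 3 lung groups, 2320 genes were higher and 2487 lower in exAM. These comparisons share the exAM libraries. Independent calls would give 133.7 and 182.3 shared genes, a value that leaves out the shared libraries, and simulated groups without differences gave 0, a value that leaves out the differences. Of the genes called against HostAM, 47.3% were higher, and 35.2% with scaling by library size alone.

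**Figure D3:**
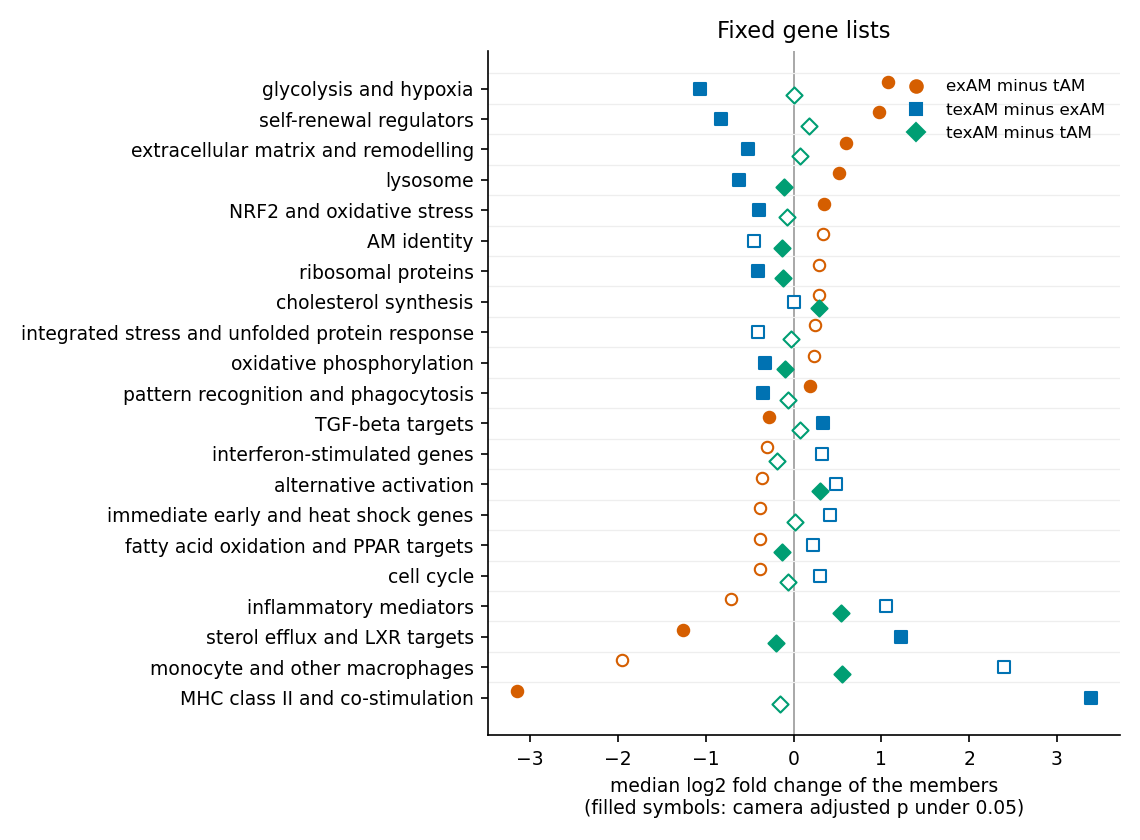
Median log2 fold change of the tested members of 21 fixed gene lists in 3 comparisons, with filled symbols for camera adjusted p under 0.05 at the preset correlation. The medians of exAM minus tAM run from -3.15 (MHC class II and co-stimulation) to 1.08 (glycolysis and hypoxia), and those of texAM minus tAM from -0.20 to 0.55.

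The third comparison, texAM against tAM, asked what of the culture was left after 4 months in a lung. A single gene passed, Arap2, a GTPase-activating protein of the actin cytoskeleton (ENSMUSG00000037999, chromosome 5, 62602445 to 62766159). It was at 19.7 ± 5.25 CPM in texAM and 2.25 ± 0.549 CPM in tAM, 8.90-fold higher (log2 3.13, adjusted p = 0.0373), and at 111.5 ± 8.74 CPM in exAM. Several genes that had separated exAM strongly were close in both transplanted groups, such as Csn2 with 0 counts, Fn1 at 1453 ± 68.5 and 1426 ± 115 CPM, Krt79 at 169 ± 27.2 and 199 ± 9.85 CPM, H2-Eb1 at 137 ± 11.4 and 174 ± 17.2 CPM, and Ccnd1 at 15.7 ± 0.131 and 14.3 ± 1.80 CPM. Others were less close, though not called. Mmp12 was at 45.3 and 42.2 CPM in the texAM libraries and 27.4 and 15.7 CPM in those of tAM. Il7r was at 87.2 and 75.2 CPM in texAM, 20.1 and 27.2 CPM in tAM and 382.1 and 305.7 CPM in exAM. No member of the alveolar identity list passed, and its median was -0.13. The retained share of the culture difference, as the slope over the 6417 genes called in exAM against HostAM, was -0.0083. Over the 3034 genes higher in exAM it was 0.0803 and over the 3383 genes lower in exAM it was -0.0569, while the median log2 difference of texAM over tAM, with a prior count of 2, was 0.04 and -0.05 in these sets. The value near 0 thus joined 2 slopes of opposite sign and does not by itself show that nothing was kept. The genes lower in exAM included lymphocyte transcripts such as Cd3e and Cd4, whose means were higher in texAM than in tAM. How far such transcripts moved the slope was not tested. With 1 texAM or tAM library at a time, from log2 CPM with that prior count, the slope over all called genes ran from -0.0093 to 0.004. It was -0.017 without tAM replicate 2, -0.0231 without HostAM replicate 1, 0.0076 without HostAM replicate 2, -0.0027 without texAM replicate 1 and -0.0015 without exAM replicate 2. With the other pair of contrasts, exAM over tAM and texAM over HostAM, it was -0.0407, and without a filter it was -0.0228.

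Several lists shifted as groups with no member called over all genes. Cholesterol synthesis genes were higher in texAM (median 0.29, adjusted p = 2.19e-07), with 3 of 24 members called adjusted over the list alone. So were inflammatory mediators (median 0.54, 3 of 27 adjusted over the list alone), alternative activation (median 0.30, 1 of 16) and markers of monocytes and other macrophages (median 0.55, 3 of 27), with adjusted p = 3.83e-08, 0.00316 and 0.00212. Lower in texAM were alveolar identity (adjusted p = 0.000531), sterol efflux and LXR targets (median -0.20), fatty acid oxidation and PPAR targets (median -0.13), oxidative phosphorylation (median -0.10), lysosome (median -0.11) and ribosomal proteins (median -0.12), with 0 members called adjusted over the list alone and adjusted p = 0.000453 to 0.048. None of the 10 lists was called with an estimated correlation, where cholesterol synthesis had adjusted p = 0.0715, inflammatory mediators adjusted p = 0.105, alternative activation adjusted p = 0.192, sterol efflux adjusted p = 0.27, fatty acid oxidation and monocyte markers adjusted p = 0.42, alveolar identity and lysosome adjusted p = 0.633, oxidative phosphorylation adjusted p = 0.643 and ribosomal proteins adjusted p = 0.664. Without texAM replicate 1 only the lists of cholesterol synthesis, inflammatory mediators, sterol efflux and alternative activation were called, and fatty acid oxidation and monocyte markers (adjusted p = 0.0641), lysosome (adjusted p = 0.0722), alveolar identity (adjusted p = 0.181), ribosomal proteins (adjusted p = 0.187) and oxidative phosphorylation (adjusted p = 0.392) were not. Without genes over 0.5 counts per base alveolar identity (adjusted p = 0.0759), lysosome (adjusted p = 0.159) and oxidative phosphorylation (adjusted p = 0.189) were not called, while self-renewal regulators (adjusted p = 0.024), pattern recognition (adjusted p = 0.00534) and matrix genes (adjusted p = 0.029) were called higher. Oxidative phosphorylation was called in 9 of 18 alternatives, and not with a minimum of 50 counts (adjusted p = 0.081), library size alone (adjusted p = 0.0575), counts corrected for filled positions (adjusted p = 0.0565) or a fit of the 4 libraries (adjusted p = 0.0568). Without tAM replicate 1 alternative activation (adjusted p = 0.0869), monocyte markers (adjusted p = 0.192) and oxidative phosphorylation (adjusted p = 0.102) were not called, and without tAM replicate 2 ribosomal proteins (adjusted p = 0.103) and oxidative phosphorylation (adjusted p = 0.0854) were not, while self-renewal regulators (adjusted p = 0.000515) and matrix genes (adjusted p = 0.0436) were called higher. Self-renewal regulators were also called higher without texAM replicate 2 (adjusted p = 0.037), HostAM replicate 1 (adjusted p = 0.0462) or HostAM replicate 2 (adjusted p = 0.0488) and with a minimum of 50 counts (adjusted p = 0.0396). Lymphocyte markers moved in the same direction as the lists that were higher, with a median of 1.35 and 3 of 12 members called adjusted over the list alone, and so did granulocyte markers with a median of 0.63.

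The edgeR test gave 1139 genes at an unadjusted p under 0.05, and the DESeq2 Wald test called 64 genes, Arap2 among them. Arap2 was also called without a filter, with a minimum of 50 counts, with DESeq2 size factors and with library size alone. The 95% interval of the fold change lay within 2-fold for 8104 genes, 55.7% of those tested, so for the others a difference of 2-fold or more was not excluded. Arap2 was not called without tAM replicate 1, tAM replicate 2, texAM replicate 1, exAM replicate 1 or exAM replicate 2, and neither with the replicate number as a block (adjusted p = 0.0957), with counts corrected for filled positions (adjusted p = 0.0799) or in a fit of the 4 libraries (adjusted p = 0.0535), with log2 changes of 2.83 to 3.39 in these. The counts of called genes without those 5 libraries were 0, 0, 0, 1 and 0, and they were 2, 5 and 5 without texAM replicate 2, HostAM replicate 1 and HostAM replicate 2.

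Against resident cells, texAM differed in 48 genes, 36 higher and 12 lower, and tAM in 6 genes. Of the members of the fixed lists, Cd4, Mmp12 and Cish were called. Cd163l1, a scavenger receptor cysteine-rich protein known from gamma-delta T cells (chromosome 7, 140218267 to 140231145), was at 50.6 ± 3.32 CPM in texAM, 17.4 ± 7.26 CPM in tAM and 0.566 ± 0.177 CPM in HostAM. Ermn was at least 97.8-fold higher, the liprin gene Ppfia4 276-fold (counting interval 49.1 to 10900), Adam12 98.3-fold (counting interval 26.9 to 817) and the transcription factor Hlf 67.8-fold. Mmp12, of the macrophage and matrix lists, was at 43.8 ± 2.20 CPM against 18.4 ± 2.16 CPM, and Cish, a feedback inhibitor of cytokine signalling, was 1.95-fold higher. Lower in texAM were Clca1, a gene of mucous cells, at 1.83 ± 0.811 CPM against 116 ± 120 CPM in HostAM, Ctse, Wdfy1, Mtus1 and Plekha6. Lymphocyte markers were higher in texAM as a list, with a median of 1.72 and 5 of 12 members adjusted over the list alone, Cd4 at 71.4 ± 12.4 CPM against 5.59 ± 4.95 CPM (adjusted p = 7.47e-06, and adjusted p = 0.294 with an estimated correlation).

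In tAM, Ppfia4 (chromosome 1, 134296783 to 134332928), Cd163l1 and the membrane transporter-like gene Mfsd6 were higher than in HostAM, Mfsd6 at 117 ± 2.90 CPM against 45.1 ± 6.24 CPM. The aspartic protease Ctse (chromosome 1, 131638306 to 131675505) was at 1.22 ± 0.407 CPM against 48.1 ± 2.03 CPM, Wdfy1 fell 3.18-fold, and the organic cation transporter Slc22a4, chosen after its values were seen, was at 0.295 ± 0.240 CPM against 7.19 ± 1.05 CPM. Ppfia4, Cd163l1 and Mfsd6 were higher and Ctse and Wdfy1 lower in both transplanted groups, in comparisons that share the HostAM libraries. Independent calls would give 0.007 and 0.002 shared genes and simulated groups without differences gave 0, and neither value allows for shared libraries and differences at once, so the overlap was not read as a shared effect. Ptprc was at 727 ± 94.7 CPM in HostAM and 735 ± 24.3 CPM in texAM (adjusted p = 0.977).

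Among the lists, NRF2 genes were lower in texAM (median -0.21, 0 of 27 members called, 1 adjusted over the list alone, adjusted p = 5.35e-05) and in tAM (median -0.14, 5 lower adjusted over the list alone, adjusted p = 1.99e-05) than in HostAM, with adjusted p = 0.572 and 0.641 with an estimated correlation. Inflammatory mediators were higher in texAM (median 0.32, 3 of 27 adjusted over the list alone, adjusted p = 0.00526, and adjusted p = 0.572 with an estimated correlation). Class II and co-stimulation genes were higher in tAM (median 0.21, 5 of 16 higher and 1 lower adjusted over the list alone, adjusted p = 0.00367, and adjusted p = 0.506 with an estimated correlation), as were ribosomal proteins (median 0.11, adjusted p = 0.0431, and adjusted p = 0.802 with an estimated correlation). Inflammatory mediators were not called without texAM replicate 1 (adjusted p = 0.193) or HostAM replicate 1 (adjusted p = 0.0803), and class II genes were not without tAM replicate 2 (adjusted p = 0.062) or HostAM replicate 1 (adjusted p = 0.0613), nor ribosomal proteins without these (adjusted p = 0.363 and 0.0613) or HostAM replicate 2 (adjusted p = 0.169). Lists that gained a call in some alternatives were, for texAM, lysosome and sterol efflux (lower, lowest adjusted p = 0.0234), interferon-stimulated genes (lower, adjusted p = 0.0213), cholesterol synthesis (higher, adjusted p = 0.0234) and glycolysis and hypoxia (higher, adjusted p = 0.038), and for tAM, alveolar identity (higher, lowest adjusted p = 0.0201) and cholesterol synthesis (lower, lowest adjusted p = 0.0147). Transcripts of lung epithelium were lower in tAM (median -0.51, adjusted p = 0.000189) and texAM (median -0.23, adjusted p = 0.0331) than in HostAM, and those of red cells and platelets by medians of -1.09 and -0.53, with adjusted p of 0.229 and 0.294 for both lists with an estimated correlation. Dendritic cell markers were lower in tAM (median -0.55, adjusted p = 0.0124, and adjusted p = 0.229 with an estimated correlation) and texAM (median -0.36, adjusted p = 0.0461, and adjusted p = 0.294 with an estimated correlation), and granulocyte markers were higher in texAM (median 0.55, adjusted p = 0.0304, and adjusted p = 0.294 with an estimated correlation). Leaving out texAM replicate 1 left 1 called gene for texAM against HostAM, Cd163l1. Without texAM replicate 2, HostAM replicate 1 and HostAM replicate 2, 8, 15 and 90 genes were called, of which 6, 13 and 32 were among the 48. The DESeq2 Wald test called 379 genes for texAM and 176 for tAM. For tAM, 1 gene was left without tAM replicate 1, 0 without tAM replicate 2 (edgeR, 1457 genes at an unadjusted p under 0.05 with all libraries), 3 without HostAM replicate 2, and 9, 16 and 26 genes were called without HostAM replicate 1, texAM replicate 1 and texAM replicate 2, with 4, 6 and 6 of the 6 among them.

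**Figure D4:**
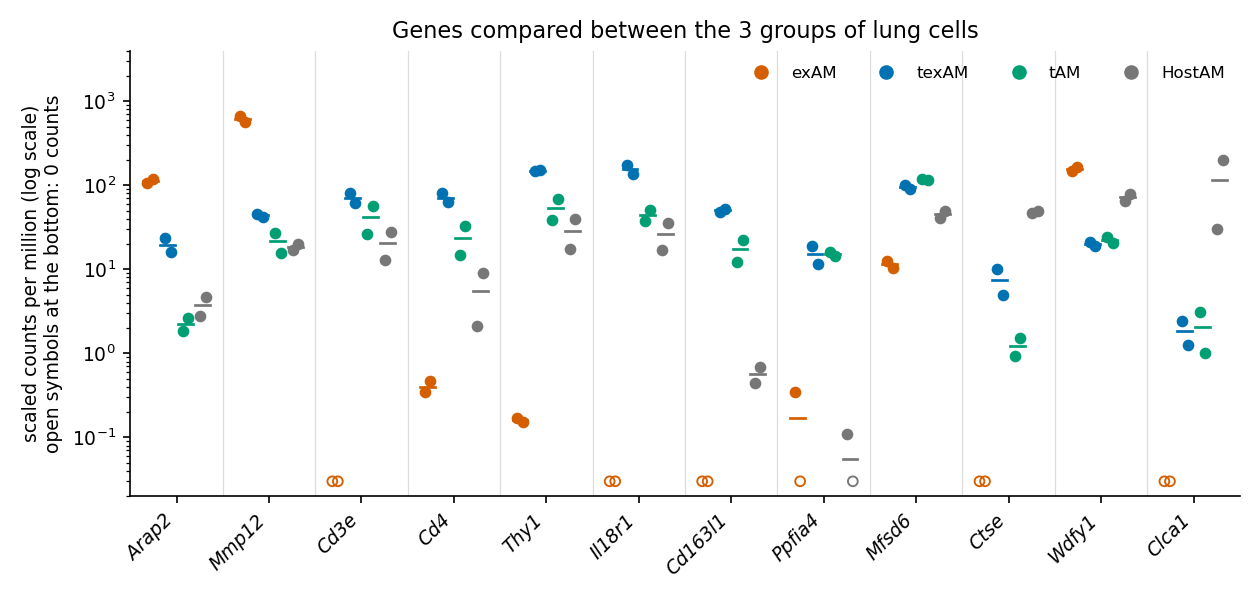
TMM-scaled CPM on a log axis for 12 genes, 1 point per library and a line at the mean of each group (n = 2), with Thy1 and Il18r1 shown, beside the lymphocyte markers Cd3e and Cd4, after their values were seen. Arap2 in texAM (19.7 ± 5.25 CPM) lies between tAM and exAM, and these 4 genes have their highest mean in texAM.

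The table itself had a limit at high counts. Of 10226 genes with a mean of at least 50 counts, 0 exceeded 2 counts per base of their longest transcript in any library, and the highest value was 1.94. The 226 tested genes over 1 count per base had a median log2 ratio of exAM over the lung libraries of -0.15 in unscaled counts and 0.36 after scaling. Within the 6 lung libraries their median log2 count rose by 0.21 per unit of log2 library size (95% interval 0.08 to 0.34), against 1.15 (1 to 1.29) for 5270 genes of 0.05 to 0.25 counts per base.

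**Figure D5:**
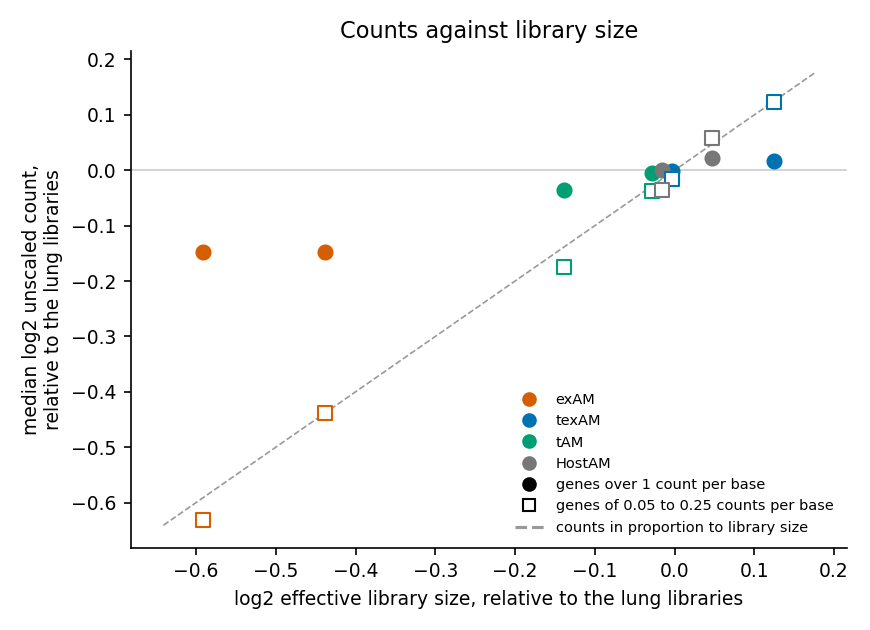
Median log2 unscaled count of 226 genes over 1 count per base (filled circles) and of 5270 genes of 0.05 to 0.25 counts per base (open squares) against log2 effective library size, both relative to the lung libraries, 1 symbol of each kind per library. The squares follow the dashed line of proportion, and the circles stay between -0.15 and 0.02.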

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

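The tests in this part were chosen after the results they concern had been seen. Arap2 was singled out because its difference from HostAM was not the same in the 2 transplanted groups. It was higher by 2.40 on the log2 scale in texAM and by -0.73 in tAM, and the difference between these was 3.13 (adjusted p = 0.0373). HostAM cancels in that difference, so it is the comparison of texAM with tAM over again and not a separate test. The call was lost without tAM replicate 1 (adjusted p = 0.505) or 2 (0.207), texAM replicate 1 (0.24), or exAM replicate 1 (0.0855) or 2 (0.103). With groups of 2 libraries, no library was tested for lying far from its group.

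Of the 36 genes called higher in texAM than in resident cells, 21 were under 1 CPM in exAM, against 15.2% of all tested genes, and 35 also had a higher mean in tAM than in HostAM. From the fixed lymphocyte list 6 T cell members were taken (Cd3d, Cd3e, Cd3g, Cd4, Trbc2 and Lck). Cd8a, not among these, was at 1.5 and 2.2 CPM in texAM and 1.5 and 17.2 CPM in HostAM. Il7r, also not among these, was at 87.2 and 75.2 CPM in texAM and 9.6 and 33.2 CPM in HostAM. The 6 members had a median log2 change of 2.44 in texAM over HostAM (1.02 to 3.68) and 1.06 in tAM over HostAM. Of these, Cd3d, Cd3e, Cd3g and Trbc2 had 0 counts in exAM. RNA of T lymphocytes is a candidate source for part of these genes, although the gate for SiglecF and CD11c and the sort for the donor's CD45 would remove T cells of the recipient, and exAM brought none of those 4 transcripts. Where such RNA would come from, and a change in the macrophages themselves, stay open. Only 1 of these 36 calls was left without texAM replicate 1.

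Unchanged cultured cells in the texAM libraries could not account for Arap2, since its level would need a share of 16% of exAM RNA, at which 5 genes of exAM that are at 0 in tAM and HostAM would give 2345 counts in texAM, and 6 were found (Csn2 had 0 where 930 were expected). RNA of T cells, whose own Arap2 level was not measured, cannot be told apart from a change in the macrophages. The log2 change of Arap2 in texAM over tAM exceeded the median of the 6 T cell members by 1.78, but its lower limit of 2.38 lay under the highest upper limit among them, 3.99. An earlier test, of Arap2 in exAM, could not decide this and was replaced. A remnant of the cultured state may also explain Arap2, which was found and tested on the same libraries.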

How the results depend on the processing

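The slope from log2 CPM with a prior count of 2 and the 2 alternatives on filled positions were chosen after seeing the data. No gene called in any comparison was called in the opposite direction under any alternative. Of 5180 values of named genes 4904 (94.7%) kept their side of the threshold, 276 lost the call with the direction kept and 0 reversed with a call. Directions were not compared where neither fit made a call. Named genes, apart from Ptprc, were picked as called in the main fit, so these shares do not describe all called genes. Of the 48 genes called for texAM against HostAM, 56.2% kept the call with the replicate number as a block. The counts for exAM against tAM, texAM against exAM and exAM against HostAM moved by more than 1.5 times only with a 2-fold minimum (3807, 3651 and 3740). The small counts depended on the processing. Without a filter they were 238 (texAM against tAM), 694 (texAM against HostAM) and 425 (tAM against HostAM), with 5 and 5 lists in the last 2 and a slope of -0.0228, and with DESeq2 they were 64, 379 and 176. A minimum of 50 counts gave 106 and 44 for the comparisons with HostAM, where fewer genes were tested. The replicate number as a block gave 0 (texAM against tAM) and 29 (texAM against HostAM), and equal numbers did not pair libraries (correlations of -0.061 to 0.009). Counts corrected for filled positions gave 0 for texAM against tAM, fits of 4 libraries gave 2 (Il18r1 and Il7r, not Arap2), and leaving out genes over 0.5 counts per base gave 1 list for tAM against HostAM. With an estimated correlation the called lists numbered 1, 1, 0, 1, 0 and 0 over exAM against tAM, texAM against exAM, texAM against tAM and exAM, texAM and tAM against HostAM. Without a filter the lists of self-renewal and TGF-beta targets lost their calls in texAM against exAM (adjusted p = 0.0847 and 0.192), and TGF-beta targets and pattern recognition in exAM against HostAM (adjusted p = 0.167 and 0.0788). Oxidative phosphorylation lost its calls in texAM against exAM and exAM against HostAM with a minimum of 50 counts, library size alone, fits of 4 libraries and genes over 0.5 counts per base left out (adjusted p = 0.0751 to 0.114). Leaving out those genes also ended the calls of NRF2 genes in texAM against exAM (adjusted p = 0.0915) and of class II genes (adjusted p = 0.291) and ribosomal proteins (adjusted p = 0.134) in tAM against HostAM. The slope was -0.0407 with the other pair of contrasts and -0.0027 with the prior count of 2. Leaving out 1 library, where the lone library left is assumed to vary like the other groups, gave 4698 to 6881, 4471 to 6796, 0 to 5, 4591 to 6169, 1 to 90 and 0 to 26 genes in that order, 8 to 10, 9 to 13, 4 to 11, 9 to 11, 1 to 4 and 1 to 5 lists, and slopes of -0.0231 to 0.0076. The cause of the other shifts was not tested. Depth set a floor of 0.328 to 0.458 CPM for 3 counts in a library, scaled here by total counts without TMM. On the TMM scale used elsewhere the floor was higher in exAM (factors 0.8917 and 0.9119) and lower in lung libraries (1.021 to 1.048).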

Other observations

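The tests of a limit per position and of chromosome 1 were chosen after the results had been seen, while those of proportion to depth and of the lysosomal genes were written before theirs. Xist, transcribed from the inactive X chromosome, was at 801 and 1058 CPM in the exAM libraries and 1329 to 1759 CPM in the lung libraries, and Ddx3y had 55 and 59 counts in exAM and 0 in each lung library. The sex of the donors is not stated for the pools. Eif2s3y, Kdm5d and Uty were also counted in both exAM libraries. The lung libraries had 0 counts of these genes, apart from 2 of Uty in HostAM replicate 2. The exAM pools thus held RNA of male cells that the lung pools did not show beyond those counts. What share of exAM this RNA made up was not measured. Each comparison of exAM with a lung group, and the slope, includes that difference.

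Genes of over 1 count per base were higher in exAM after scaling and not before. Sampling of reads in proportion to depth does not describe them, since their slope on library size in the lung libraries was 0.21 (0.08 to 0.34) and not 1. A limit of 1 read per start position and strand, as left by removal of duplicate reads, is a candidate explanation. The unscaled log2 ratio of exAM over lung was -0.149, where the slope in the lung libraries forecast -0.11 (-0.17 to -0.04). This forecast replaced a first form of the test, a ratio within 0.1 of 0, which the value had missed, and an earlier test of the variance over the mean, 10.56 on average for genes over 1.5 counts per base against a Poisson limit of 0.86, had not separated the explanations.

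Higher lysosomal transcripts in exAM were also seen where positions were free. The median log2 change of the 11 lysosomal genes under 0.5 counts per base was 0.85, with 63.6% of them called, so a limit on counts does not explain the whole list, and for members over 1 count per base the 2 explanations stay open. Of the 226 genes over 1 count per base, 126 were called higher and 29 lower in exAM than in tAM.

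Genes that differed between donor cells and HostAM lay on chromosome 1 more often than others. Of 41 genes called for tAM and texAM against HostAM, 10 (24.4%) lay there, against 5.6% of tested genes (Fisher's exact p = 6.64e-05, odds ratio 5.49, 2.39 to 11.5), and their median distance to Ptprc was 6.6 Mb against 46.7 Mb for other tested genes of that chromosome. A segment of another strain around the CD45 allele in Ly5.1 mice is a candidate explanation for the 7 that lay within 25 Mb. Wdfy1, Tgfb2 and Mfsd6 lay 58.4, 48.6 and 85.4 Mb away, and a segment of that reach would not cover them. Among the 7, Lamc1 was at 104.6 and 106.4 CPM in texAM, 56.2 and 58.8 CPM in tAM and 40.3 and 43.1 CPM in HostAM. A segment shared by both donor groups would not give its difference between texAM and tAM, which was not called. Loss of the recipient's reads at variants from the reference could not give the 6 genes of chromosome 1 that were higher in HostAM. For the 4 that were lower there it cannot be told apart from lower expression, since 1 of them had over 3 counts in HostAM at less than 50% of the donor level.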
